A study of Mus musculus with 3 samples.

How the data were processed

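Dorsal root ganglion cells came from male ICR mice of 8 to 10 weeks, per the labels, and were cultured for 72 hours before RNA was taken. RNA was extracted with TRIzol and the SV Total RNA kit and labelled with biotin using the GeneChip WT Pico kit, per the submitters' labels, and each medium has 1 array. The values used are the intensities deposited by the authors, summarised in Affymetrix Expression Console per the submitters' processing notes. The software version, the summarisation and normalization methods and the genome build are not given in the sources used here. Raw array images were not used here. The values run to 496402 and are not logarithms, so log2(value + 1) was used throughout, and every difference is a log2 difference between 2 arrays.

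The gene lists, the floor, the thresholds of 2-fold, 1.5-fold and 3-fold, the rules for naming genes and the scaling alternatives were fixed before the data were examined. Genes were named by the deposited annotation of the probe sets: 30604 of 65956 probe sets have a single symbol, 2146 have several and 33206 have none. Of the single symbols, 827 were updated through their gene numbers with a mouse RefSeq table (GRCm38.p6), which was used for names only. Where a gene had more than 1 probe set (355 of 30142 genes), the one with the highest mean was kept. Nrp1 and Calca, which were to be named in every case, have no probe set with a single symbol and are not analysed here. The floor is the 95th percentile of the mean log2 values of 492 vomeronasal receptor genes, taken as unexpressed in this tissue, and came to 5.48 (43.7 intensity units); 17653 genes lay at or above it.

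For each difference the 12 highest and 12 lowest genes above the floor were named, leaving out, by the form of their symbols, predicted genes, RIKEN clone genes, microRNA genes, small nuclear, nucleolar and Cajal body RNA genes, 5S ribosomal and similar RNA genes, pseudogenes, and vomeronasal, olfactory, immunoglobulin and T cell receptor genes. Other noncoding RNA genes, such as AF357426 and the Y RNA genes, were kept. In the lists the members furthest apart were named, and 11 genes with measured values, among them Plxnd1 and the nociceptor genes, were named in every case. The lists were written from general knowledge: 1244 distinct symbols, of which 1062 were measured and 842 lay above the floor, and the 49 of 51 lists with at least 5 members above the floor were placed among 10000 random lists drawn from 20 bins of mean brightness. A list stood apart below percentile 1 or above percentile 99.

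Because 48 or 49 of the 49 list medians were 0, the list mean and the balance of members higher and lower were added after the data were seen, which raised the number of percentiles from 147 to 441. The threshold at a ratio of 5 to 4, the count without microRNA and other unnamed kinds of gene, and the exchange of each gene's values among the arrays were also added after the data were seen. So were a count with values below the floor set to the floor, and the matrix genes without Mmp13. A shift of the scale gives all identical members of a list the same sign, so directions under other scalings (centring, loess, quantile normalization, an offset of 16) were counted among the members that differ in the deposited values, also an addition. Of 45, 38 and 39 lists with a direction in the 3 comparisons, 39, 34 and 35 kept it under every scaling. Under some scaling 2, 3 and 2 turned, and the rest did neither.

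The method was tried on the comparison of SEMA3E with control, with each gene's values first exchanged among the 3 arrays and shifts then put in by computer. Of 50 genes shifted by 2-fold 50 were found, and of 50 shifted by 1.5-fold 48. A gene counted as found slightly below its own shift, so these are not the shares that would pass the thresholds of 2-fold and 1.5-fold. All 50 shifted lists stood apart by the median, 42 by the mean and 50 by the balance, while of 200 unshifted lists 0, 1 and 2 did. In each shifted list most members were lowered by the same amount, whereas medians of random lists lay at 0. Standing apart by the median and the balance was therefore built in. These counts do not show how often lists with fewer shifted members would be found. The shifts were added to summarised values, so this trial cannot show differences lost in the summary. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.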

Results

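RNA from dissociated dorsal root ganglion neurons of adult male ICR mice, an outbred strain, was measured on 3 arrays after 72 hours in culture. The ganglia hold the cell bodies of sensory neurons, together with satellite glia, Schwann cells, fibroblasts and macrophages. One array came from cells in control medium (DMEM with the B27 supplement). A second came from cells given 1 µg/ml recombinant semaphorin 3E (SEMA3E), a secreted guidance protein that acts through the receptor plexin D1. The last came from cells given the same SEMA3E together with 1 µg/ml of an IgG that blocks it. There are no replicates, so no difference below has a test or an error, and the number of arrays limits the precision of every value.

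Each array held 65956 probe sets, and its values ran from about 6 to 496402 intensity units with a median between 44.5 and 45. Of the genes named by a single-symbol probe set, 17653 had a mean at or above the background floor of 43.7 units. The 3 arrays were close to each other: Pearson's r across these genes, which are not independent replicates, lay between 0.9996 and 0.9997. In 74.9% of the genes all 3 arrays held an identical value, in 17.3% a pair of arrays did, and in 7.79% all 3 differed. An identical value does not show that the RNA was equal, because the summary of the probes into 1 value can hide small differences.

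The first comparison, SEMA3E against control medium, asked which transcripts of sensory neurons differ after exposure to SEMA3E. Mmp13, a collagenase that cleaves fibrillar collagen (probe set TC0900000044.mm.1), was the protein-coding gene furthest apart, with 722 units in control medium and 280 with SEMA3E, a log2 difference of −1.36. Txnip, which binds thioredoxin and limits glucose uptake, was lower in the SEMA3E array (log2 difference −0.84), as were Sostdc1, a secreted antagonist of BMP and Wnt signals (−0.71), and the matrix proteoglycan gene Ogn (−0.57). Eid3, a relative of inhibitors of the acetyltransferase EP300, was higher (0.77), as were the neuronal membrane protein gene Slitrk6 (0.56) and the glutathione transferase gene Gsta4 (0.50). RNA of Plxnd1, the receptor of SEMA3E, was slightly higher (0.14), and that of Sema3e itself was 5.93 on the log2 scale in all 3 arrays, near the floor of 5.48.

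Of the 17653 genes 7 differed by at least 2-fold between SEMA3E and control, 4 higher and 3 lower with SEMA3E. Apart from Mmp13 they were 5 microRNA genes and 1 predicted gene, of kinds the naming rule leaves out, and they are named here after their values were seen. Mir99a (−2.04) and Mir376b (−1.61) were lower with SEMA3E, where their values of 4.92 and 4.71 lay below the floor, so that the floor itself gives only −1.48 and −0.84, and Mir6920 (1.38), Gm22935 (1.18), Mir181b-2 (1.10) and Mir8115 (1.00) were higher. Among the 30 genes at least 1.5-fold apart, 17 were microRNA genes, which make up 1.81% of the genes above the floor. The remaining genes named as lower with SEMA3E were the small noncoding RNA gene AF357426 (−0.64), Fxyd7 (−0.51), which encodes a regulator of the sodium pump, Neto1 (−0.48), an auxiliary subunit of glutamate receptors, the histone gene H3c7 (−0.46), the glial receptor gene Gpr37l1 (−0.45), Bcl2a1a (−0.45), Ctla2a (−0.44) and the transcriptional co-regulator gene Cited2 (−0.43). Those named as higher were the defensin genes Defb46 (0.64) and Defb39 (0.51), the ubiquitin ligase gene Cbl (0.46), S100a8 (0.41), the succinate receptor gene Sucnr1 (0.39), S100a4 (0.35), the myeloid lectin gene Clec4d (0.35), Ptgs2 (0.29), which encodes cyclooxygenase 2, and the quinone reductase gene Nqo1 (0.28). H3c7, Defb46, Defb39, Bcl2a1a and Ctla2a belong to families of closely related genes, whose probes can read more than 1 member, Defb39 lay below the floor in control medium, and a second probe set of Cbl gave 0.00.

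**Figure D1:**
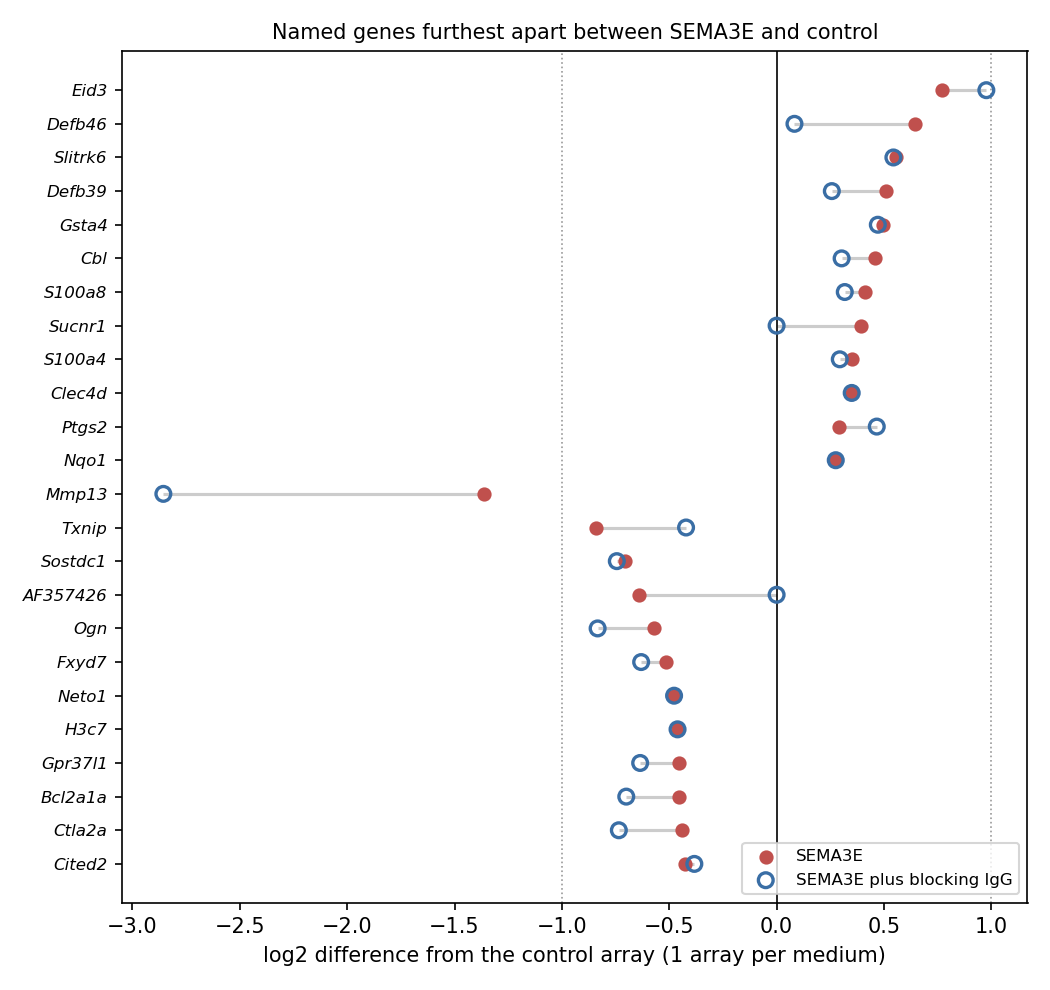
The 24 named genes furthest apart between SEMA3E and control are listed on the vertical axis, and the horizontal axis gives the log2 difference from the control array, as a filled point for the SEMA3E array and an open circle for the array with SEMA3E and blocking IgG (1 array per medium, dotted lines at 2-fold). Mmp13 lay at −1.36 and −2.86, while Sucnr1 and AF357426 differed from control with SEMA3E and stood at the control value with the IgG.

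Neuronal genes that differed between these arrays were mostly slightly lower with SEMA3E. Of 23 pan-neuronal markers above the floor, 12 were lower, 11 identical and 0 higher, and at least 9 of these 12 stayed lower under each scaling, among them Tubb3 (−0.16), the neuronal beta-tubulin, Syp (−0.12), a synaptic vesicle protein, and the neurofilament genes Nefl (−0.06) and Nefm (−0.06). Their median difference of −0.0024 lay at percentile 0.24 among 10000 random lists matched on brightness, although their mean of −0.026 lay at percentile 15.1 and the median turned to 0.0038 after centring and 0.0070 after loess, where the identical members take the sign of the shift. This was the single list of 49 whose median stood apart, since the medians of the other 48 were 0. Of 12 large-diameter neuron markers, 5 were lower and 0 higher, led by Pvalb (−0.38), the calcium-binding parvalbumin of proprioceptors, and Gfra3 (−0.28). Gfra3 was put in this list beforehand but also marks peptidergic nociceptors, so the lean of the list does not rest on large-diameter neurons alone. Of 19 neurotrophic factors and receptors 7 were lower and 0 higher, including the neurotrophin receptor gene Ngfr (−0.13), Ret (−0.09) and Lifr (−0.08). Lists of synaptic release genes (8 of 32 lower, 0 higher; Sv2b −0.18) and of cytoskeleton and growth cone genes (12 of 35 lower, 0 higher; Dpysl2 −0.15) leaned the same way without standing apart. Bright genes in general did so too: in the brightest sixth of genes 29.1% were lower and 7% higher with SEMA3E.

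Genes of pain sensing differed little. Of the nociceptor markers, 3 of 12 peptidergic ones were lower (Adcyap1 −0.14, Gal −0.11, Kit −0.09), and of 15 non-peptidergic ones 3 were higher and 1 lower (Mrgprx1 0.22, Ret −0.09, Nts 0.08). Gfra3, a gene of peptidergic nociceptors counted in the large-diameter list, was lower by more than these (−0.28). Tac1 at 8.68 on the log2 scale, Trpv1 at 6.24, Scn10a at 9.08 and P2rx3 at 12.78 held identical values in all 3 arrays, and Scn9a, the sodium channel NaV1.7, lay at 11.45 in control medium and 11.42 with SEMA3E. In the lists of sodium, potassium and calcium channels, 2 of 10, 2 of 23 and 1 of 16 members were lower and 0 higher (Kcna1 −0.07, Scn4b −0.03, Cacnb4 −0.03). Of 21 TRP, ASIC, HCN, Piezo and P2X channels 1 was lower (Piezo2, −0.0023, higher after centring and loess), of 18 glutamate and GABA receptors 2 were lower (Gabbr2 −0.05, Gabra2 −0.02), and all 11 opioid, cannabinoid and monoamine receptors were identical. The injury and regeneration list had 1 of 32 members higher and 10 lower (Sez6l −0.13), while Atf3, an injury-induced transcription factor, stayed at 14.45. Among 20 immediate-early genes 4 were lower and the rest identical (Ier5 −0.17 and below the floor with SEMA3E, Ier2 −0.17).

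Most inflammatory genes were identical in the SEMA3E and control arrays, as were 14376 of all 17653 genes. All 9 pro-inflammatory cytokines and all 17 members of the NF-kappaB list were, with Il6 at 6.86. Of 15 chemokines 12 were identical, Cxcl13 was higher (0.12), and Ccl2 lay at 10.95 in control medium and 10.97 with SEMA3E. Of 12 genes of the prostaglandin, bradykinin and histamine pathway, Ptgs2 (0.29) and Ptges (0.03) were higher and 0 lower. Interferon-stimulated genes had 1 of 22 higher and 3 lower (Cmpk2 −0.27, Stat2 −0.12), and antigen presentation genes 1 of 13 lower (Psmb10 −0.25). Toll-like receptor and inflammasome genes had 3 of 17 higher and 1 lower (Tlr7 0.11, Saa3 −0.09), cytokine and chemokine receptors 1 of 16 higher and 2 lower, and complement genes 1 of 8 higher (C3ar1 0.08). Markers of other cells went both ways: macrophage markers had 3 of 13 higher and 1 lower (Lyz1 0.20, Lyz2 0.19, Cd68 −0.08), lymphocyte, mast cell and neutrophil markers 2 of 5 higher (S100a8 0.41, S100a9 0.15), and satellite glial markers 2 of 15 higher and 4 lower (Fbln5 −0.28, Atp1b2 −0.26, Kcnj10 −0.24, Fabp7 0.13).

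Among the remaining groups, NRF2 antioxidant genes leaned higher with SEMA3E, with 6 of 22 higher and 2 lower (Gsta4 0.50, Nqo1 0.28, Gsta2 0.12, Mt3 −0.24). Extracellular matrix and remodelling genes had 4 of 31 higher and 6 lower (Mmp13 −1.36, Mmp2 −0.35, Tnc 0.23), and fibroblast markers 2 of 17 higher and 3 lower (Ogn −0.57, Mgp 0.25). Oxidative phosphorylation genes had 13 of 50 lower and 0 higher (Cox6b1 −0.22, Cox6a1 −0.19, Ndufa3 −0.15), a balance ordinary for lists of that brightness (percentile 21.5). By the balance of members higher and lower, a statistic added after the medians came out at 0, pan-neuronal, large-diameter neuron and neurotrophic genes stood apart as lower on the deposited scale (percentiles 0.085, 0.465 and 0.45) and NRF2 genes as higher (percentile 99.9), but each of the 4 lay within the band under at least 1 other scaling. By the list mean, also added later, NRF2 genes (percentile 99.2), lymphocyte, mast cell and neutrophil markers (percentile 99.5) and matrix genes (percentile 0.94, but 75.2 without Mmp13) stood apart.

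The second comparison, SEMA3E with blocking IgG against SEMA3E alone, asked what the antibody alters in the presence of SEMA3E. Mmp13 was lower again with the IgG, at 98.9 against 280 units (log2 difference −1.49), so that its level moved further from control. Single noncoding RNA genes were higher with the IgG: the ribosomal RNA gene Rn28s1 (0.44), the Y RNA genes Rny3 (0.43) and Rny1 (0.38, and 0.24 by its second probe set), the neuronal cytoplasmic RNA Bc1 (0.40, but 0.12 by its second probe set) and the mitochondrial ribosomal RNA mt-Rnr1 (0.34). With SEMA3E alone the same genes lay below control, by log2 differences of −0.31, −0.28, −0.24, −0.29 and −0.19 in that order. Second probe sets gave −0.28 for Rny3, −0.10 for Rny1 and −0.12 for Bc1. These genes were named for lying above the SEMA3E array, so values below control in that array partly follow from the choice. Txnip (0.42), the Notch ligand gene Jag1 (0.38) and the thrombospondin gene Thbs1 (0.37) were higher as well. The retinoic acid binding protein genes Crabp2 (−0.53) and Crabp1 (−0.30), Cdh1 (−0.35), which encodes E-cadherin, and the orphan receptor gene Gpr151 (−0.32) were lower.

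Mmp13 and Mir376b (1.45) were the 2 genes that differed by at least 2-fold, and Mir376b lay below the floor with SEMA3E alone, with 0.68 left when counted from the floor. At 1.5-fold there were 24 genes, 14 higher and 10 lower, of which 9 were microRNA genes. Other genes named as lower with the IgG were Speer4c (−0.62) and Speer4e (−0.55), from a family of closely related genes, Defb46 (−0.56), Sucnr1 (−0.39), Calhm5 (−0.35), the potassium channel gene Kcnj10 of satellite glia (−0.30) and Hspb2 (−0.30). Named as higher were AF357426 (0.64), the histone genes H2ac10 (0.44) and Hist1h2aj (0.39), Hmgn5 (0.41) and the mitochondrial gene ND2 (0.39). Plxnd1 was 0.22 higher with the IgG than with SEMA3E alone.

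No list median stood apart between these arrays, since all 49 were 0. By the balance of members, oxidative phosphorylation genes were lower with the IgG, 21 of 50 lower and 1 higher (Ndufa6 −0.14, Ndufb3 −0.13, Ndufa1 −0.12). This lay below all 10000 random lists, and their mean of −0.023 lay at percentile 0.49. Random lists treat genes as independent, so a list whose genes vary together can stand apart through a chance deviation of 1 array. Neurotrophic factors and receptors were in their counts the reverse of the first comparison, with 7 of 19 higher and 0 lower (Ngfr 0.13, Gfra3 0.13, Lifr 0.08; percentile 99.9). The members were not all the same: Cntfr (−0.03) was lower in the first comparison and identical here, and Fgfr1 (0.03) was higher here and identical there. Such a reversal has no error attached and shares the SEMA3E array with the first comparison, so a chance deviation of that array would give it as well. Macrophage markers had 5 of 13 lower and 1 higher (Lyz1 −0.20, Lyz2 −0.08, Cd68 0.08; percentile 0.615), but did not stand apart after loess or quantile normalization. Pan-neuronal markers were split, 5 of 23 higher and 3 lower (Map2 0.09, Avil 0.07, Stmn2 −0.07), and 4 each way under loess and quantile scaling. Cell proliferation genes had 7 of 32 higher and 1 lower (Plk1 0.11, Racgap1 0.09), and the cytoskeleton list 8 of 35 higher and 1 lower (Actb 0.15, Dpysl2 0.15). In the channel lists 1 of 10 sodium channels was higher and 1 lower, 1 of 23 potassium channels was lower (Kcnk1 −0.07), and all 16 calcium channels were identical. Of 32 injury genes 4 were higher and 5 lower with the IgG, among the lower ones Gal (−0.30), Npy (−0.20) and Crh (−0.19). That balance was ordinary for lists of equal brightness (percentile 35.1). Among cytokines, 1 of 9 was lower (Il18 −0.04), and among immediate-early genes 4 of 20 were higher (Arc 0.32, Ier5 0.17).

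**Figure D2:**
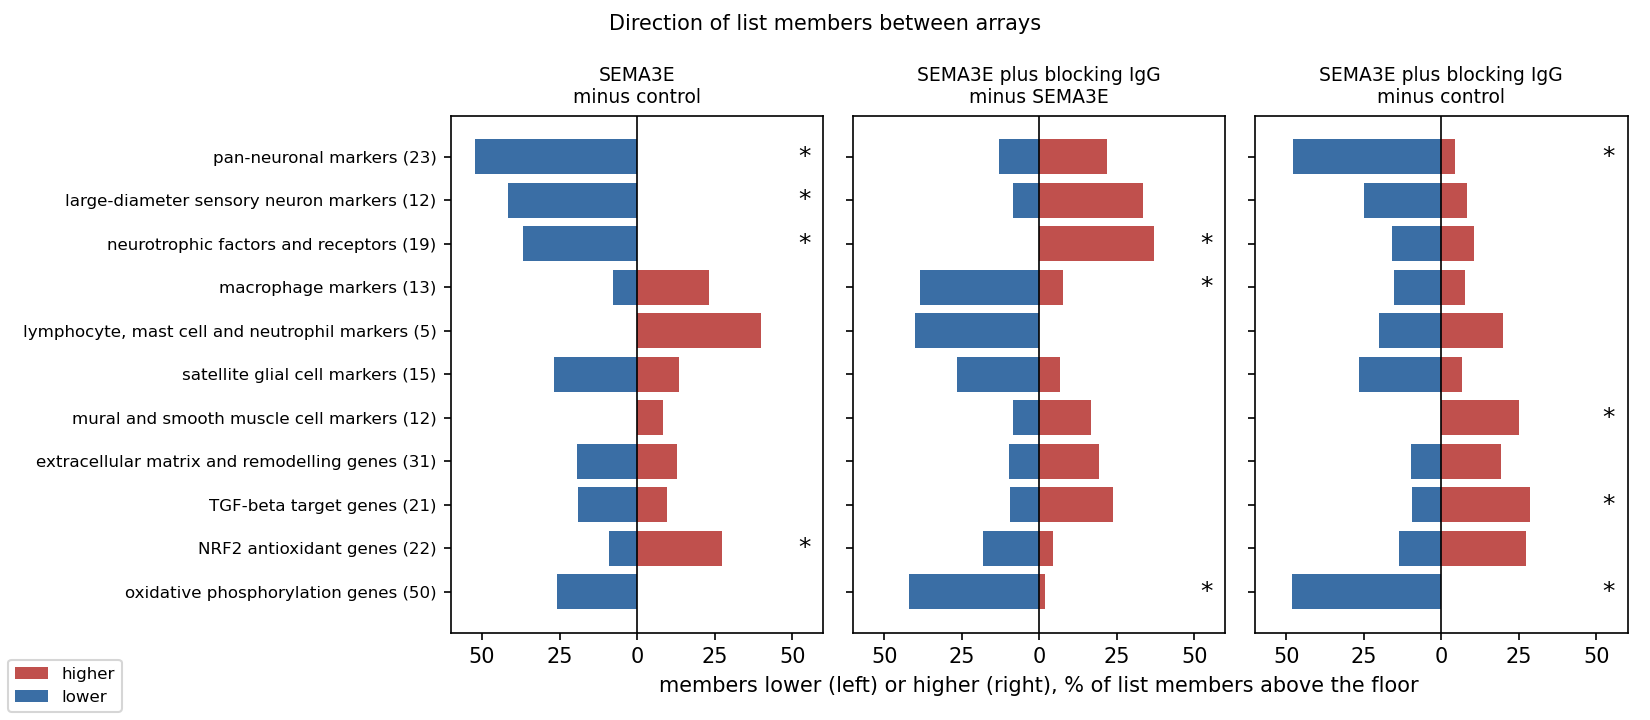
Each row is a gene list that stood apart by its median, mean or balance of members in at least 1 comparison (number of members above the floor in brackets), and each panel is a comparison of 2 arrays, with bars to the right for the percent of members higher and to the left for the percent lower; the rest were identical. Asterisks mark lists outside percentiles 1 to 99 by the balance of members, such as the oxidative phosphorylation list, with 24 of 50 members lower in the last panel.

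The comparison of SEMA3E with blocking IgG against control medium asked which differences from control remained with the antibody present. Mmp13 was again furthest apart, at 98.9 against 722 units (log2 difference −2.86). Ogn (−0.83), Sostdc1 (−0.74), Ctla2a (−0.73), Bcl2a1a (−0.70), Crabp2 (−0.68), Gpr37l1 (−0.64) and Fxyd7 (−0.63) were lower, as were Pmp2, a myelin protein gene (−0.57), Cdr1 (−0.57), Ifitm3 (−0.57) and Speer4c (−0.89). Eid3 (0.98), Jag1 (0.64), Slitrk6 (0.54), Gsta4 (0.47) and Ptgs2 (0.47) were higher. Plxnd1 was 0.35 higher, at 10.88 against 10.53 on the log2 scale.

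Of the 17653 genes 3 differed by at least 2-fold, all lower: Mmp13, Mir99a (−1.19) and Mir340 (−1.15). At 1.5-fold there were 36, 11 higher and 25 lower. The other genes named as higher were Kctd16 (0.36), Thbs1 (0.36), Gldn (0.36), Clec4d (0.35), the macrophage elastase gene Mmp12 (0.33) and the collagen gene Col12a1 (0.33).

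No list median stood apart here either. By the balance of members, 24 of 50 oxidative phosphorylation genes were lower and 0 higher (Ndufb3 −0.25, Ndufa3 −0.24, Cox6b1 −0.24), below all 10000 random lists, and 11 of 23 pan-neuronal markers were lower and 1 higher (Tubb3 −0.16, Syp −0.12, Map2 0.08; percentile 0.165). At least 20 of these 24 genes and 9 of these 11 markers were lower under each scaling. After quantile normalization, however, the balances lay at percentiles 7.38 and 32.0 and no longer stood apart. The array with IgG is shared with the second comparison, so a deviation of that array could lower oxidative phosphorylation genes in both. Mural and smooth muscle markers (3 of 12 higher, 0 lower; Tagln 0.22, Myl9 0.10; percentile 99.2) and TGF-beta target genes (6 of 21 higher, 2 lower; Ccn1 0.12, Tgfb3 0.12, Tgfbi −0.20; percentile 99.3) stood apart as higher, but not after centring, loess or quantile normalization. By the list mean, satellite glial markers (−0.077, percentile 0.55; Kcnj10 −0.54, Fbln5 −0.30, Atp1b2 −0.26) stood apart as lower, but with 4 of 15 lower, 1 higher and 10 identical their balance did not (percentile 16.3). The mean of the 31 matrix genes also did (−0.071, percentile 0.34), through Mmp13 alone: 6 were higher and 3 lower (Thbs1 0.36, Mmp2 −0.38), and without Mmp13 the mean was 0.022 (percentile 98.2). All 21 TRP, ASIC, HCN, Piezo and P2X channels were identical in these arrays, as were 8 of 9 cytokines and 16 of 17 NF-kappaB genes (Tnfaip3 0.10).

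**Figure D3:**
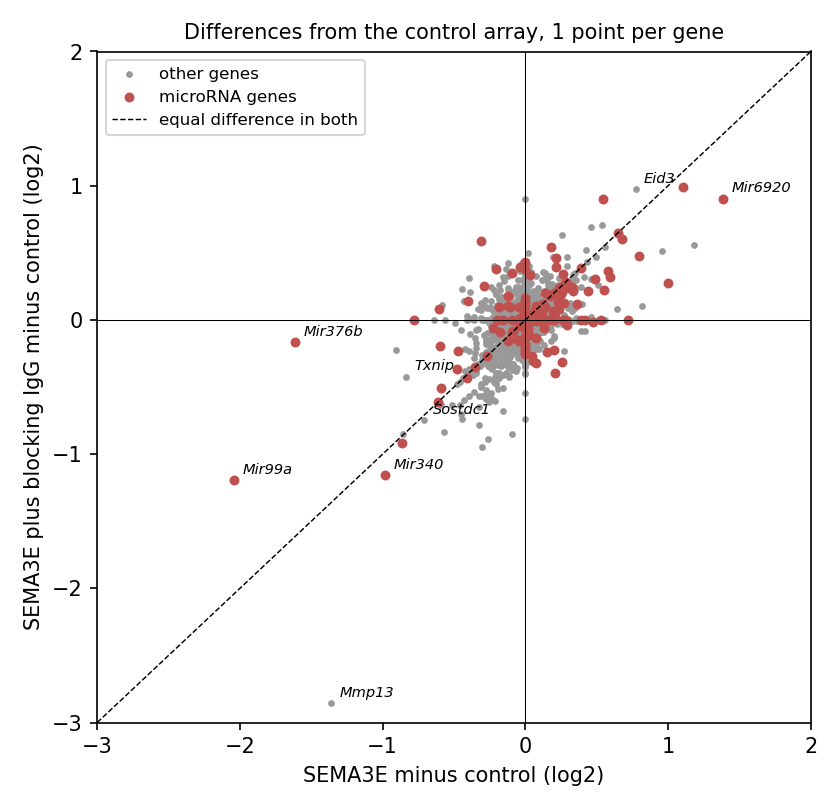
Each point is 1 of 17653 genes, with the log2 difference of the SEMA3E array from control on the horizontal axis and that of the array with SEMA3E and blocking IgG on the vertical axis, microRNA genes in red and the dashed line marking equal differences. Mmp13 lay at −1.36 and −2.86, and Mir376b at −1.61 and −0.16.

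The last comparison asked whether genes that differed with SEMA3E lay nearer the control level once the blocking IgG was added. Of the 7 genes at least 2-fold apart between SEMA3E and control, 3 did (42.9%): Mir376b, Mir8115 and Gm22935. Mmp13 was further from control, and Mir99a, Mir6920 and Mir181b-2 lay nearer the SEMA3E level. At 1.5-fold 12 of 30 genes lay nearer control (40%), and at a ratio of 5 to 4, a threshold added after the counts were seen, 55 of 129 (42.6%). When the 3 values of each gene were exchanged among the arrays at random, in 1000 draws, the share was 50% with a range from 32.1% to 68.0% at 1.5-fold and from 41.6% to 57.7% at 5 to 4 (central 95% of draws). The observed shares were thus no higher than those with exchanged values. The count of genes at least 2-fold apart between SEMA3E and control, 7, lay above the range with exchanged values (median 4, from 2 to 6). At 1.5-fold the count of 30 was the median with exchanged values (from 23 to 36). Because the exchange was made for each gene separately, its ranges treat the genes as independent. The roles of the arrays were also turned, so that the array with IgG was compared with control and SEMA3E alone was the array in between. The share was then 33.3% of 3 genes at 2-fold, 41.7% of 36 at 1.5-fold and 49.4% of 156 at 5 to 4.

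No protein-coding gene passed 2-fold and lay nearer control. At 1.5-fold Defb46 (0.64 above control with SEMA3E and 0.08 with the IgG) and AF357426 (−0.64 and 0.00) lay near control with the IgG, and Txnip (−0.84 and −0.42) lay midway between the other arrays. Genes were also sought in which the other 2 arrays lay within 0.5 of each other on the log2 scale while the remaining array stood at least 2-fold above or below both, which leaves out Mmp13 and Mir99a, whose 3 values all lay further apart. There were 0 for control, 1 for SEMA3E (Mir376b, by a value below the floor) and 0 for the array with IgG, but with low values set to the floor there was 1 for control and 0 for SEMA3E. At 1.5-fold, under the same condition, the counts were 11, 9 and 6, against a median of 9 for each array with exchanged values. The differences of both SEMA3E-containing arrays from control correlated across genes with r = 0.534, and with exchanged values, where only the shared control array links them, r was 0.504 with a range from 0.421 to 0.569. Their covariance was 0.0025, against 0.0023 with exchanged values, and without Mmp13 it was 0.0023.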

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

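Probe sets with several symbols or none lay outside the named genes, and some were further apart between arrays than any named gene. Of 15401 such probe sets above the floor, 25 differed by at least 2-fold between SEMA3E and control (19 higher and 6 lower with SEMA3E), against 7 of 17653 named genes. Between SEMA3E with blocking IgG and SEMA3E alone 27 did (5 higher, 22 lower with the IgG), and between SEMA3E with IgG and control 27 did (20 higher, 7 lower). The furthest lay at log2 differences of 3.16 and −2.15, of 1.96 and −3.54, and of 1.72 and −2.77 in the same order, while Mmp13 reached −2.86. They have no single gene to name them by, and the cause was not tested.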

How the results depend on the processing

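The number of genes at least 2-fold apart between SEMA3E and control, 7, depended on the choices made. It was 30 at 1.5-fold, 2 at 3-fold and 3 with a filter at the 60th percentile of brightness. Among second probe sets it was 0, but only 355 genes have one, not Mmp13, so 0 says little here and below. With choices added after the data were seen it was 129 at 5 to 4 and 1, Mmp13, without genes left out of naming. Quantile normalization gave 6 (3 higher, 3 lower) and an offset of 16 gave 5 (2 higher, 3 lower). Values below the floor set to the floor gave 6 (4 higher, 2 lower). Between SEMA3E with IgG and SEMA3E alone the count of 2 became 24 at 1.5-fold, 0 at 3-fold, 1 with the brightness filter, 1 among second probe sets, 138 at 5 to 4, 1 without genes left out of naming and 1 with low values set to the floor. Between SEMA3E with IgG and control the count of 3 became 36 at 1.5-fold, 1 at 3-fold, 1 among second probe sets, 156 at 5 to 4 and 1 without genes left out of naming.

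The number of lists standing apart between SEMA3E and control, 1 by the median, was 3 with the brightness filter, 3 after quantile normalization and 2 after loess. It was 3 by the mean and 4 by the balance of members. Among second probe sets it was 0, but these left only 3 list results over all comparisons, against 147 in the chosen form. For SEMA3E with IgG against SEMA3E alone the count of 0 became 1, 1 and 2 with the brightness filter, quantile normalization and loess, 1 by the mean and 3 by the balance. Against control it became 1 after loess, 2 by the mean and 4 by the balance. Of the 11 places by the balance, those of oxidative phosphorylation genes and of neurotrophic factors and receptors with IgG against SEMA3E alone stayed outside the bounds under all 4 other scalings, and the remaining 9 did not.

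The median of pan-neuronal markers for SEMA3E minus control, −0.0024, was 0.0038 after median centring, 0.0070 after loess and −0.00076 after quantile normalization, where the 11 identical members take the sign of the shift; of the 12 that differ, 10, 9 and 9 stayed lower. Bc1, which was 0.11 higher with SEMA3E and IgG than in control, was −0.0044 by its second probe set. Across all choices 4669 of 4713 values of named genes moved by less than the SD of all genes in that comparison (0.066, 0.066 and 0.071), 43 moved by more and 1 turned. Of this total, 681 without the filter on low values, 597 with the brightness filter and most with the mean of all probe sets could not move. Centring shifted each comparison by 1 constant. Among second probe sets, 13 values stayed within that SD, 16 moved by more and 1 turned. Of 202 genes with 2 probe sets above the floor, 34, 35 and 41 differed by both, in the order above. Of these 32, 35 and 40 shared the sign. The others of the 202 were identical by at least 1 probe set and not compared.

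The single gene in which the SEMA3E array stood apart from both others, these lying within 0.5, became 9 at 1.5-fold, 0 at 3-fold, 0 with the brightness filter, 0 among second probe sets, 45 at 5 to 4, 0 without genes left out of naming and 0 with low values set to the floor. The count for control, 0, became 1 with low values set to the floor and 1 when the other arrays could lie within 1 of each other. The share of genes nearer control with IgG, 42.9%, was 66.7% (2 of 3) with the brightness filter, 14.3% (1 of 7) when at least 80% of the difference had to be gone, and 0 of 1 gene (Mmp13) without genes left out of naming, while second probe sets left no gene to count. No paired analysis was possible because each medium has 1 array. The scale and the filter changed which small differences counted, and the cause was not tested.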

Other observations

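Of 50 oxidative phosphorylation genes 21 were lower and 1 higher with the IgG than with SEMA3E alone, and 13 were lower with SEMA3E than in control, the latter no more than in random lists (percentile 21.5). The genes were not always the same: Ndufb3 (−0.12 and −0.13) and Ndufa3 (−0.15 and −0.09) were lower in each, Cox6a1 (−0.19) in the first and Ndufa6 (−0.14) in the second. Several genes differed from control by similar amounts in both SEMA3E-containing arrays, among them Slitrk6 (0.56 and 0.54), Gsta4 (0.50 and 0.47), Nqo1 (0.28 and 0.28), Sostdc1 (−0.71 and −0.74) and Pvalb (−0.38 and −0.39). At a ratio of at least 5 to 4, 22 genes lay above control in both arrays and 36 below, where exchanged values gave 22 (15 to 30) and 29 (21 to 37), so a shared control array alone leads to counts of this size.

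MicroRNA genes held identical values in all 3 arrays in 47.2% of 320 cases, the other genes left out of naming in 59.0% of 5327 and genes kept for naming, such as Trpv1, in 82.6% of 12006, with median log2 values of 6.75, 7.34 and 8.16. Tests chosen after the result was seen asked whether the summary of probes or rounding could give the ties. A median polish of 3 simulated unchanged arrays left 56.6% of probe sets identical at 20 probes, and from 0 to 87.6% over the probe numbers tried, so this summary, at first read as a sufficient reason, might account for the ties or not, depending on probe numbers not given in the sources used here. Rounding was tested in 3 forms: a share of distinct values over all probe sets (39.2%) that left rounding possible, that share split by brightness (9.86% dim, 94.9% bright), and last the share of unequal pairs closer than 10% of their median difference. That share was 5.15%, but 3.85% among dim probe sets, short of the bound of 5% set for excluding rounding. Rounding to a step leaves no smaller difference. The smallest unequal difference was 3.0e-05 on the log2 scale and 9.5e-05 among dim probe sets, where the medians were 0.077 and 0.070. These values argue against rounding of all values to a coarse step. Rounding in a finer step, or of some values only, could still play a part.

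The difference of Mmp13 was −1.36 from control to SEMA3E and −1.49 from there to SEMA3E with IgG. Tests chosen after the result was seen asked whether fewer stromal cells or 1 deviating array could be the reason. The mean difference of 42 other fibroblast and matrix genes between SEMA3E with IgG and control was 0.0019 with an SD of 0.172, with 7 higher, 4 lower and the rest identical. A loss of the cells that express them as large as the −2.86 of Mmp13 is thus an unlikely reason, though Ogn reached −0.83. A smaller loss is not excluded, because identical values can hide small differences. The smaller of the successive steps was −1.36, but these steps are the pattern itself and no spread between cultures is known, so 1 or more deviating arrays may be the reason. SEMA3E or the IgG could be the reason as well, but no array had the IgG without SEMA3E. An IgG that merely failed to block SEMA3E would leave Mmp13 near the SEMA3E level only if cultures varied little, which is not known.

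Tubb3, Syp and other pan-neuronal markers were lower in the SEMA3E array, 12 of 23 with 0 higher. Tests chosen after the result was seen asked whether the scale of bright probe sets or fewer neurons could be the reason. The balance of members lay at percentile 0.085 of lists equally bright, and at least 9 of the 12 stayed lower under each scaling, but the balance lay at percentile 1.32 after loess scaling and 46.9 after quantile normalization, so a difference of scale could be the reason and is not excluded. Fewer neurons would leave markers of other cells relatively higher, and 2 of 6 such lists had more members higher than lower, 3 had more lower and 1 was level, which leaves that reading open. In all 6 lists together 9 of 78 members such as Lyz2 (0.19) were higher and 10 such as Fbln5 (−0.28) lower.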
